A study of Mus musculus with 6 samples.

How the data were processed

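Messenger RNA libraries from mouse palatal shelves at E14.25 were analysed, 3 wild type and 3 labelled as a neural crest cell knockout of Kmt2d. Per the labels' protocols, the shelves were frozen in Trizol and the RNA was made into libraries with a stranded mRNA-seq kit and sequenced as paired 25 bp reads. TopHat2, SAMtools, HTSeq and the mouse build mm9 are named in the submitters' processing notes, without versions. The gene annotation, the multiple-alignment setting and the strand setting used for counting are not given in the sources used here. The deposited values are the authors' raw counts of read pairs per gene symbol, 1 file per library, not normalised and not pooled.

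Each file listed 23366 genes under symbols of an older annotation and 5 category lines of the counting program. The category lines stayed out of library sizes and tests. Pairs outside annotated genes made up 14.8%, 15.4% and 12.3% of the listed total in wild type replicates 2, 3 and 4 and 18.1%, 47.5% and 14.2% in knockout replicates 1, 2 and 3. Pairs with more than one alignment made up 18.4%, 20.7% and 20.99% in the wild type and 30.3%, 18.1% and 27.7% in the knockout, and ambiguous pairs 0.168% to 0.439%. The 95% Wilson intervals of the shares outside genes and of Rn45s were at most 0.0215 percentage points to either side. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Without a stated strand setting, genes that overlap on opposite strands could share counts, and reads that align to several copies of a gene were set aside as not unique, so values of multicopy genes such as histones and ribosomal proteins are uncertain. Genome coordinates are not printed, because the annotation used here is of another build than the counts.

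Groups and replicate numbers were taken from the sample titles. Same-group libraries differed by more than sampling noise in each pair, with a chi-square per degree of freedom from 11.5 to 160, so no pair was taken for 1 library deposited more than once. This does not show separate animals, and the 6 libraries were used as replicates because the labels describe them so. The labels name no batch, litter or date. Xist counts were 46581 in wild type replicate 3 and 70941 in knockout replicate 2 and at most 36 elsewhere, while Ddx3y counts were 1 and 0 in these libraries and at least 1284 elsewhere. Each group thus held 1 library with this pattern, and the sex-linked list (Xist, Ddx3y, Eif2s3y, Kdm5d and Uty) was not named as a result.

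Counts were normalised by the trimmed mean of M-values and filtered by edgeR's filterByExpr, which left 14233 genes. The groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust, current method) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. CPM values are counts scaled by the normalised library size, and log2 fold changes are knockout over wild type with a standard error from the fitted model. The design, the gene lists and the rule for named genes were fixed before the data were examined. The 28 lists tested covered the KMT2C/D complex, palate, bone, cartilage, tendon and tooth programmes, signalling pathways, markers of other cell types and cell states. Of their 620 distinct genes, 6 were not named in the files and 59 were named but too low to test. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Camera ranks a list against all other genes, whereas fry asks whether the genes of the list move without comparing them with others.

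Genes were named by the following rule. Kmt2d was always named, with any complex member past the threshold. The 12 largest rises and 12 largest falls past the threshold were named if their mean was at least 1 CPM and the groups did not overlap. Predicted genes, unnamed cDNA clones and the sex-linked list were left out, but other genes of the sex chromosomes were kept. From each list up to 4 members past the threshold were named, or else the 1 member with the smallest p, as values. Hba-a1, Hbb-b1, Myog, Epcam, Pecam1, Csf1r and Sox10 were named as markers of other cells. Genes named beyond this rule are said to be chosen after their values were seen.

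Shares of reads between groups were compared with two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. The alternatives planned were other size factors (median of ratios, upper quartile), DESeq2 1.42.0, limma voom, the earlier edgeR quasi-likelihood method, no filter and a filter of 1 CPM in 3 libraries, leaving out each library, the replicate number as a block, and a test against a 1.2-fold change. Added after seeing the data were voom with sample quality weights, leaving out Rn45s and Lars2, and removal of each library's trend with GC content and transcript length. GC content, length and genomic span came from GENCODE and RefSeq annotation of a later mouse build, matched by symbol and synonym, with span for 22611 of 23366 genes and without span for 409 more. The gene test was tested on simulated counts for 14233 genes of this comparison, 200 of them changed. It recovered 65.7% of the genes changed by 1 on the log2 scale, 88.1% at 1.5 and 92.4% at 2, with 10 false calls among 174. These counts were drawn independently for each gene at the fitted trend of dispersion, with no library standing apart as knockout replicate 2 does. The rates therefore do not give the power or error of the test in the data. In a simulation with the neuronal list raised 2-fold, 1 of 28 lists passed. Its genes were drawn independently, whereas the estimated correlation in the data reached 0.933 in the skeletal muscle list. The simulation therefore does not show how often lists of correlated genes pass at the preset correlation.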

Results

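RNA-seq counts were analysed from palatal shelves dissected from E14.25 mouse embryos. The palatal shelves are the paired outgrowths of the maxillary processes that meet and fuse to form the secondary palate, and most of their mesenchyme descends from the cranial neural crest. The samples fell into 2 groups, 3 wild type libraries and 3 libraries labelled as a neural crest cell knockout of Kmt2d. Kmt2d encodes a histone methyltransferase whose human counterpart is mutated in Kabuki syndrome. The comparison addresses how its loss from the neural crest alters gene expression in the developing palate. The labels number the wild type libraries 2, 3 and 4 and the knockout libraries 1, 2 and 3, and describe the samples of each group as separate biological replicates.

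Read pairs assigned to genes totalled 24916079, 20785074 and 21965460 in wild type replicates 2, 3 and 4, and 18902786, 12721979 and 20203309 in knockout replicates 1, 2 and 3. Of all pairs listed in the files, genes received 65.4% ± 1.62 (SD, n = 3) in the wild type and 47.8% ± 12.2 (SD, n = 3) in the knockout. That difference gave p = 0.1 in a two-sided exact permutation test, the smallest value that 3 against 3 libraries allow. In knockout replicate 2, 47.5% of the pairs fell outside annotated genes, against 12.3% to 18.1% in the other 5 libraries. The feature Rn45s, which carries ribosomal RNA sequence, took 18.9% ± 2.38 (SD, n = 3) of the gene counts in the wild type and 27.9% ± 8.47 (SD, n = 3) in the knockout (two-sided exact permutation test, p = 0.3). Wild type libraries ranged from 16.2% to 20.7%, and knockout replicates 1, 2 and 3 stood at 35.1%, 18.6% and 30.0%. Without knockout replicate 2 the groups therefore differ in this share too. Lars2 took 1.37% ± 0.152 (SD, n = 3) in the wild type and 2.51% ± 0.801 (SD, n = 3) in the knockout (two-sided exact permutation test, p = 0.1). On principal component 1, which held 51.2% of the variance, knockout replicate 2 lay at 77.0 and the other 5 libraries between -31.0 and -1.46. Its log CPM correlated across genes with the other libraries at 0.922 to 0.942, whereas wild type libraries correlated with each other at 0.984 to 0.987 and knockout replicates 1 and 3 at 0.977. These correlations run across genes, which are not independent replicates. Counts of the group comparison are therefore also given without knockout replicate 2.

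**Figure D1:**
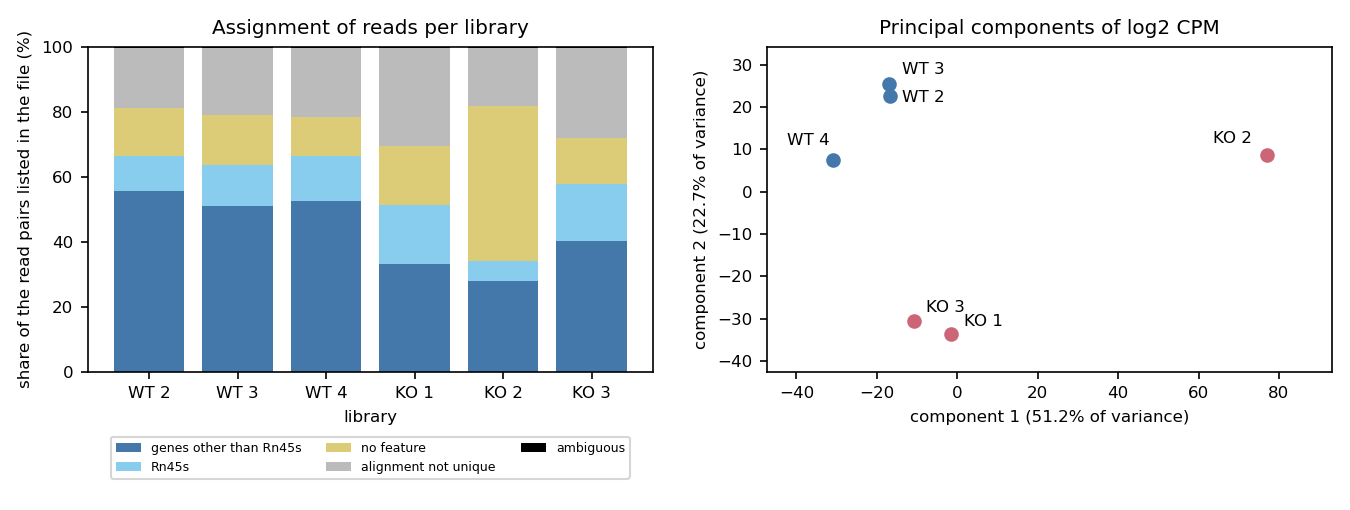
The left panel stacks, for each library, the percent of listed read pairs assigned to genes other than Rn45s, to Rn45s, to no feature, to alignments that were not unique and to ambiguous features. The right panel plots each library (wild type in blue, knockout in red) on principal components 1 and 2 of log2 CPM, where knockout replicate 2 lies at 77.0 on component 1 and the other 5 libraries lie below 0.

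The transcript of the targeted gene, listed in the files under its older symbol Mll2, showed no difference past the threshold between the groups. Kmt2d stood at 193 ± 20.6 CPM (SD, n = 3) in the wild type and 329 ± 184 CPM (SD, n = 3) in the knockout, a log2 fold change of 0.77 with a standard error of 0.35 (edgeR quasi-likelihood test, adjusted p = 0.368). The log2 fold change was 0.21 without knockout replicate 2 (adjusted p = 0.519). A count over the whole gene includes exons outside any deleted part and transcripts of cells outside the neural crest lineage, so these values do not check the knockout labels. Of the 16 tested members of the KMT2C/D complex and the related COMPASS family of histone methyltransferases, 0 passed the threshold over all genes and 0 adjusted over the list alone. Their median log2 fold change was 0.29, with 13 of 16 positive, and 0.086 to 0.38 with single libraries left out (lowest without knockout replicate 2). The member with the smallest p was Mll1 (Kmt2a), at 164 ± 16.8 CPM (SD, n = 3) in the wild type and 280 ± 121 CPM (SD, n = 3) in the knockout (adjusted p = 0.304). Its log2 fold change of 0.78 became 0.36 without knockout replicate 2, a library in which Mll1 stood at 419 CPM against 222 and 199.98 CPM in knockout replicates 1 and 3. The list ranked above other genes in the competitive test (camera, adjusted p = 0.0118), with an adjusted p = 0.44 with an estimated correlation.

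Expression of 76 genes differed between the labelled knockout and the wild type palatal shelf, and 62 of these fell while 14 rose. Pcolce, an enhancer of procollagen C-proteinase, fell from 40.6 ± 6.57 to 5.43 ± 1.74 CPM (SD, n = 3 each), and Tmem119, a membrane protein of the osteoblast lineage and of microglia, fell from 53.1 ± 4.09 to 11.3 ± 1.92 CPM (SD, n = 3 each). Gria4, an AMPA-type glutamate receptor subunit, rose from 12.1 ± 1.62 to 42.6 ± 15.2 CPM (SD, n = 3 each), and Pou3f2, a POU domain transcription factor of neural progenitors, rose from 0.0792 ± 0.0316 to 2.25 ± 1.60 CPM (SD, n = 3 each). Each of the 76 genes had all 3 knockout libraries on one side of all 3 wild type libraries. Over the 14233 genes tested, such separation occurred in 23.5%, where chance alone gives 10%.

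Among the falling genes with at least 1 CPM on average, the log2 fold changes were largest for Bpifa1, a secreted protein of airway epithelium, Lamc3, a laminin chain, Nos1, the neuronal nitric oxide synthase, Gpr30, a G protein-coupled receptor for estrogen now named Gper1, and Cpxm2, a carboxypeptidase family member. Bpifa1 had 160 counts over the wild type libraries and 1 count over the knockout libraries, a depth-adjusted ratio of 102 with a 95% counting interval of 18.1 to 4069. The log2 fold change was -4.37 for Lamc3 (SE 0.59, adjusted p = 0.0325), -3.30 for Nos1 (SE 0.35, adjusted p = 0.0194), -3.23 for Gpr30 (SE 0.35, adjusted p = 0.0195) and -3.18 for Cpxm2 (SE 0.44, adjusted p = 0.039). Pcolce had a log2 fold change of -2.90 (SE 0.25, adjusted p = 0.0127) and Tmem119 one of -2.23 (SE 0.15, adjusted p = 0.00609). Fcgrt, the heavy chain of the neonatal Fc receptor, was 5.68-fold lower (adjusted p = 0.00609), Cygb, the globin cytoglobin, 5.13-fold lower (adjusted p = 0.0375) and the water channel Aqp1 4.71-fold lower (adjusted p = 0.0113). Slc16a4, a monocarboxylate transporter family member, and Calml4, a calmodulin-like protein, were 6.85-fold and 6.01-fold lower (adjusted p = 0.0436 and 0.0405).

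Of the genes that rose, Pou3f2 had a log2 fold change of 4.66 (SE 0.77, adjusted p = 0.0471) and Slc6a17, a vesicular amino acid transporter, one of 2.49 (SE 0.35, adjusted p = 0.0391). Vstm2a was 4.45-fold higher (adjusted p = 0.0308), the secreted synaptic organiser Cbln4 3.81-fold higher (adjusted p = 0.0394), Gria4 3.52-fold higher (adjusted p = 0.0389) and the amino acid transporter Slc6a15 2.61-fold higher (adjusted p = 0.0471). Smaller rises were measured for Lrrtm3, a synaptic adhesion protein (2.22-fold), Gabra3, a GABA-A receptor subunit (2.13-fold), Lrrc4c, a netrin-G ligand (1.89-fold), Kcnj2, an inward rectifier potassium channel (1.85-fold), and Unc5c, a netrin receptor (1.75-fold), with adjusted p from 0.0296 for Lrrtm3 to 0.0478 for Lrrc4c. Without knockout replicate 2, 307 genes passed, 80 higher and 227 lower, and these included 73 of the 76. Leaving out another library left 0 genes (wild type replicate 2 or 3, edgeR, with 1103 and 1117 genes at an unadjusted p under 0.05), 3 genes (wild type replicate 4), 20 genes (knockout replicate 1) or 11 genes (knockout replicate 3). All 76 kept their sign in each of these fits, which their lack of overlap between the groups made all but certain.

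**Figure D2:**
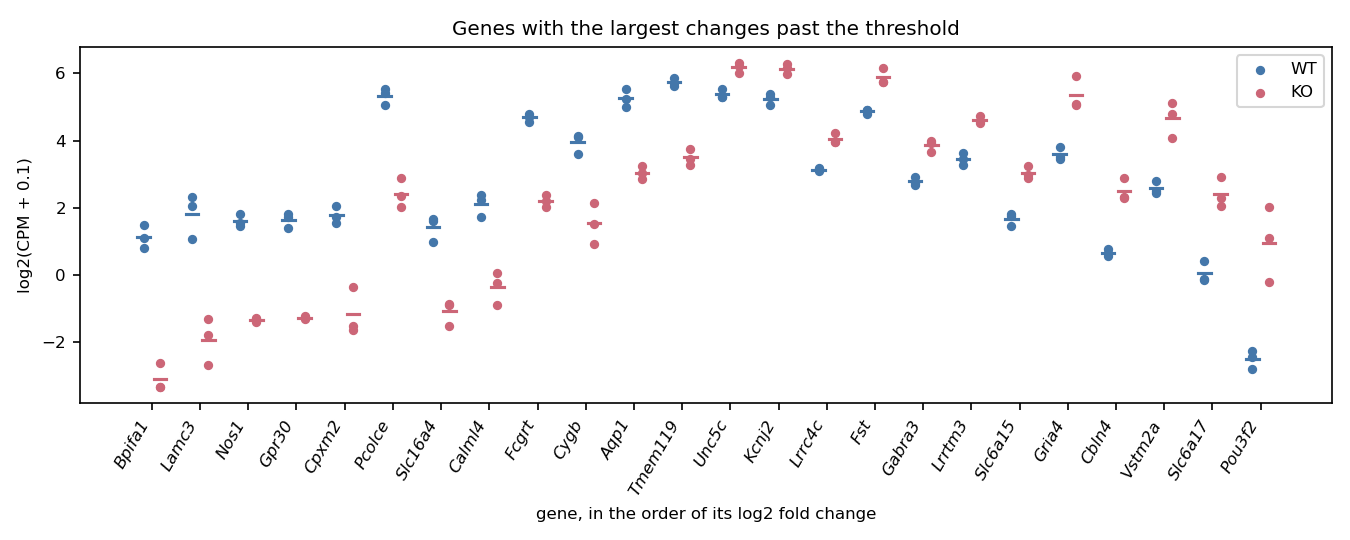
Points show log2(CPM + 0.1) of each wild type (blue) and knockout (red) library and bars the group means. Shown are the 12 largest falls and 12 largest rises past the threshold that met the naming rule, with a mean of at least 1 CPM. All 3 knockout libraries lie beyond all 3 wild type libraries for each gene, with log2 fold changes running from -6.29 for Bpifa1 to 4.66 for Pou3f2.

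Col1a1 and Sparc of the osteoblast list and Mia of the chondrocyte list fell in the knockout. Counts from whole tissue do not show which cells expressed them. Col1a1, the main collagen chain of bone, fell from 2236 ± 614 to 709 ± 108 CPM (SD, n = 3 each), 3.15-fold (adjusted p = 0.0375), and Sparc, the matrix protein osteonectin, fell from 475 ± 31.8 to 238 ± 17.96 CPM (SD, n = 3 each; adjusted p = 0.0212). Mia, a secreted protein of chondrocytes, fell from 4.74 ± 0.718 to 1.15 ± 0.311 CPM (SD, n = 3 each; adjusted p = 0.0416). Of 25 osteoblast genes tested, 0 rose and 2 fell over all genes, and 2 rose and 5 fell adjusted over the list alone. Of 24 chondrocyte genes, 0 rose and 1 fell over all genes, and 1 rose and 4 fell adjusted over the list alone. The median log2 fold changes were -0.43 for the osteoblast list (camera, adjusted p = 0.00737, and adjusted p = 0.447 with an estimated correlation) and -1.28 for the chondrocyte list (camera, adjusted p = 2.3e-06, and adjusted p = 0.44 with an estimated correlation). Among members named after their values were seen, the osteoblast regulators Runx2 and Sp7 had log2 fold changes of 0.50 (adjusted p = 0.391) and 0.11 (adjusted p = 0.955, and -0.69 without knockout replicate 2), and the chondrocyte regulator Sox9 one of 0.22 (adjusted p = 0.482). Ibsp, a gene of mineralising osteoblasts, varied within both groups, with 27.2, 15.5 and 0.856 CPM in wild type replicates 2, 3 and 4 and 0.633, 55.2 and 0.221 CPM in knockout replicates 1, 2 and 3. Col1a1 had a log2 fold change of -1.66, and of -1.83 to -1.43 with any 1 library left out (-1.70 without knockout replicate 2). It passed in none of these fits of 5 libraries (adjusted p = 0.0795 to 0.189). The osteoblast list lost its call without wild type replicate 2 (median -0.31) or knockout replicate 3 (median -0.31). The chondrocyte median was -0.66 without wild type replicate 2, whose Col2a1 stood at 880 CPM against 265 and 245 CPM in the other wild type libraries.

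**Figure D3:**
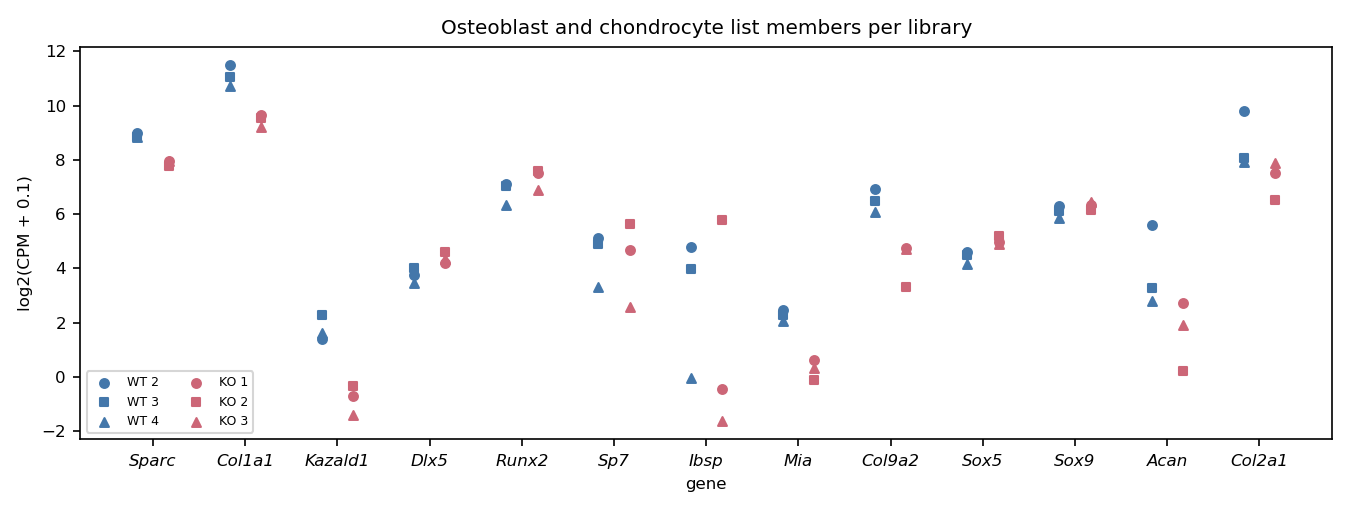
Each point is log2(CPM + 0.1) of 1 library for 13 genes of the osteoblast and chondrocyte lists, with wild type replicates 2, 3 and 4 in blue and knockout replicates 1, 2 and 3 in red. The groups separate for Sparc, Col1a1 and Mia, which fell, and overlap for Runx2, Sp7, Sox9 and Ibsp, which did not pass the threshold.

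Other connective tissue lists had few members past the threshold. Of 31 genes of extracellular matrix and shelf elevation, 0 passed over all genes, and 1 rose and 1 fell adjusted over the list alone. The smallest p in that list belonged to Bgn, the proteoglycan biglycan, at 227 ± 25.3 CPM (SD, n = 3) in the wild type and 142 ± 14.30 CPM (SD, n = 3) in the knockout (adjusted p = 0.0879, and 0.00593 without knockout replicate 2). In this list 1 member was higher and 3 were lower past the threshold without knockout replicate 2. Of 11 tendon and fascia genes, 0 passed over all genes and 3 fell adjusted over the list alone. Scx, the tendon transcription factor, stood at 9.12 ± 1.30 CPM (SD, n = 3) in the wild type and 2.79 ± 0.836 CPM (SD, n = 3) in the knockout (adjusted p = 0.0528, and 0.00975 without knockout replicate 2). Without knockout replicate 2, 2 tendon genes fell past the threshold. The tendon median of -0.12 changed sign with the library left out, from -0.58 without knockout replicate 2 to 0.072 without knockout replicate 1 and 0.24 without wild type replicate 2 (camera, adjusted p = 0.00106, 0.0537 and 0.167). Of 11 pericyte and smooth muscle genes, 0 passed over all genes and 2 fell adjusted over the list alone, with a log2 fold change of -0.94 for Cspg4 (adjusted p = 0.174). With all 6 libraries the matrix, tendon and pericyte lists had adjusted p = 0.059, 0.0526 and 0.0668 in the competitive test (camera). All 3 passed it without knockout replicate 2 (camera, adjusted p = 0.0135, 0.00106 and 0.00631, and adjusted p = 0.499, 0.364 and 0.429 with an estimated correlation). The pericyte median of -0.15 lay between -0.28 without knockout replicate 2 and -0.027 without wild type replicate 4 (adjusted p = 0.0791). The matrix median of -0.14 lay between -0.24 without wild type replicate 4 and -0.071 without wild type replicate 2 (adjusted p = 0.221). The matrix list also passed without wild type replicate 3 or 4 or knockout replicate 1 (camera, adjusted p = 0.0115 to 0.0348), the tendon list without wild type replicate 3 or 4 (0.026 to 0.0286) and the pericyte list without wild type replicate 3 (0.0166). With an estimated correlation these calls were lost (adjusted p = 0.305 to 0.572).

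In the signalling lists, single inhibitors and antagonists changed while most members did not pass. Nkd1, an intracellular WNT antagonist, fell from 27.5 ± 3.00 to 13.2 ± 1.69 CPM (SD, n = 3 each; adjusted p = 0.0391), and Hhip, a Hedgehog-binding antagonist, fell from 45.9 ± 4.64 to 21.6 ± 0.775 CPM (SD, n = 3 each; adjusted p = 0.0194). Fst, the activin antagonist follistatin, rose from 29.2 ± 1.30 to 59.7 ± 10.7 CPM (SD, n = 3 each; adjusted p = 0.0389). Of 38 WNT genes, 0 rose and 1 fell over all genes, and 1 rose and 9 fell adjusted over the list alone. The WNT list had a median log2 fold change of -0.55 (camera, adjusted p = 2.3e-06, and adjusted p = 0.276 with an estimated correlation), and 3 of its members fell without knockout replicate 2. Of 15 Hedgehog genes, 1 fell over all genes and 2 fell adjusted over the list alone, with a list median of -0.077 (camera, adjusted p = 0.15). The Hedgehog median ran from -0.23 without knockout replicate 1 to 0.14 without wild type replicate 4. The Hedgehog list passed in none of the 6 fits with a library left out (adjusted p = 0.0724 to 0.384). Of 34 BMP and TGF-beta genes, 1 rose over all genes, and 1 rose and 1 fell adjusted over the list alone, with a list median of -6.5e-04 (camera, adjusted p = 0.649). The BMP median ran from -0.0997 to 0.059 with single libraries left out. Of 24 FGF and EPH/ephrin genes, 0 passed over all genes and 0 adjusted over the list alone. The receptor Ephb2 had the smallest p of these, at 105 ± 3.00 CPM (SD, n = 3) in the wild type and 77.8 ± 6.41 CPM (SD, n = 3) in the knockout (adjusted p = 0.161, and 0.0445 without knockout replicate 2). That list had a median of 0.029, a mean of -0.014 and a downward test direction (camera, adjusted p = 0.909). Its median ran from -0.079 to 0.093 with single libraries left out.

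The epithelial list ranked below other genes in the knockout (camera, adjusted p = 1.1e-10), with a median log2 fold change of -0.52 and an adjusted p = 0.44 with an estimated correlation. Of 26 epithelial genes, 0 passed over all genes and 6 fell adjusted over the list alone, and 1 of 26 had a positive log2 fold change. The smallest p was that of Shh, the Hedgehog ligand made by palatal epithelium, at 14.7 ± 2.43 CPM (SD, n = 3) in the wild type and 6.71 ± 1.10 CPM (SD, n = 3) in the knockout (adjusted p = 0.068, and 0.022 without knockout replicate 2). The marker Epcam stood at 79.1 ± 8.54 and 53.3 ± 15.1 CPM (SD, n = 3 each; adjusted p = 0.323), a log2 fold change of -0.57 that was -0.37 without knockout replicate 2. Leaving out knockout replicate 2 gave 5 epithelial genes that fell past the threshold and a median of -0.29. Of 8 nasal epithelium genes, 1 fell over all genes, Bpifa1, and 1 rose and 6 fell adjusted over the list alone. The nasal median was -1.30 (camera, adjusted p = 4.6e-06, and adjusted p = 0.276 with an estimated correlation). Of 7 genes of salivary, pituitary or brain tissue, 0 passed over all genes or adjusted over the list alone, with a log2 fold change of -0.83 for Elf5 (adjusted p = 0.285; list median -0.15, camera, adjusted p = 0.257, and median -0.42 without knockout replicate 2).

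Markers of the remaining cell types gave no gene past the threshold. Of 18 macrophage and other leukocyte genes, 0 passed over all genes and 1 fell adjusted over the list alone. That gene was Mrc1, a mannose receptor of macrophages, at 24.9 ± 2.47 CPM (SD, n = 3) in the wild type and 12.1 ± 2.16 CPM (SD, n = 3) in the knockout (adjusted p = 0.0528, and 0.011 without knockout replicate 2). The macrophage receptor Csf1r had a log2 fold change of -0.40 (adjusted p = 0.292), and the list median was -0.61 (camera, adjusted p = 9.6e-06, and adjusted p = 0.44 with an estimated correlation). The macrophage median was -0.36 without knockout replicate 2 (camera, adjusted p = 0.00631, and adjusted p = 0.39 with an estimated correlation). Of 18 endothelial genes, 0 passed by either adjustment, over all genes or adjusted over the list alone, and 2 had positive values. Eng and Pecam1 had log2 fold changes of -0.64 (adjusted p = 0.219) and -0.29 (adjusted p = 0.317), with a list median of -0.33 (camera, adjusted p = 9.2e-04, and adjusted p = 0.446 with an estimated correlation).

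Of 13 Schwann cell and melanoblast genes, 0 passed over all genes, and 1 rose and 1 fell adjusted over the list alone. Within that list S100b had a log2 fold change of -2.30 (adjusted p = 0.161) and Sox10 one of 0.31 (adjusted p = 0.697). Sox10 was at 0.60 without knockout replicate 2 and -0.18 without knockout replicate 1. The list median was -0.11 (camera, adjusted p = 0.12, and adjusted p = 0.44 with an estimated correlation). The Schwann cell median was -0.31 without knockout replicate 2 (camera, adjusted p = 0.138) and -0.25 without knockout replicate 1, where the list passed (camera, adjusted p = 0.0141, and adjusted p = 0.445 with an estimated correlation). It was -0.038 without knockout replicate 3 (camera, adjusted p = 0.668). The lists of 19 neuronal, 27 skeletal muscle and 8 red blood cell genes had 0 members past the threshold, over all genes or adjusted over the list alone. The muscle gene Ttn stood at 10160 CPM in knockout replicate 2 and between 66.3 and 191 CPM in the other 5 libraries (adjusted p = 0.319). Myog had a log2 fold change of -0.19 (adjusted p = 0.667), and of -0.36 without knockout replicate 2 to -0.021 without wild type replicate 2. The muscle list had a median of 0.25 (camera, adjusted p = 0.358) and of -0.52 without knockout replicate 2 (camera, adjusted p = 8.6e-05, and adjusted p = 0.588 with an estimated correlation). It was 0.49 to 0.60 without wild type replicate 2 or knockout replicate 1 or 3 (camera, adjusted p = 0.00544 to 0.0445, and adjusted p = 0.727 to 0.826 with an estimated correlation). The muscle median was 0.018 without wild type replicate 3 (camera, adjusted p = 0.759). Syt1, a synaptic vesicle protein, stood at 5.34 ± 0.175 and 8.47 ± 1.74 CPM (SD, n = 3 each; adjusted p = 0.255). The neuronal list had a median of 0.059 (camera, adjusted p = 0.909), of -0.24 without knockout replicate 2 (adjusted p = 0.0548) and of 0.35 without knockout replicate 1 (adjusted p = 0.0141, and adjusted p = 0.70 with an estimated correlation). It was also below 0 without wild type replicate 2 or 4 or knockout replicate 3. The globin gene Hbb-b1 stood at 11.4 ± 3.33 and 5.37 ± 3.50 CPM (SD, n = 3 each; adjusted p = 0.389), a log2 fold change of -1.07 that was -0.63 without knockout replicate 2. The red blood cell list had a median of 0.043 and a downward test direction (camera, adjusted p = 0.795). Leaving out single libraries gave medians from -0.71 without knockout replicate 3 (adjusted p = 0.0748) to 0.43 without knockout replicate 2 (adjusted p = 0.311). Hba-a1 had 0 counts in all 6 libraries and was not tested, and Hba-a2 had at most 4 counts in any library. Reads that align to several copies of a gene were set aside, so these counts do not show that the genes were silent.

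The listed transcription factors that pattern the palate mesenchyme were not among the genes past the threshold. Of 38 cranial neural crest mesenchyme factors, 0 passed over all genes, and 2 rose and 1 fell adjusted over the list alone (median 0.19, camera, adjusted p = 0.0825). This list passed without knockout replicate 2 (median 0.24, camera, adjusted p = 0.0283, and adjusted p = 0.364 with an estimated correlation). Its median was 0.066 without knockout replicate 3 (camera, adjusted p = 0.668). Of 11 anterior palate genes, 0 passed over all genes and 2 rose adjusted over the list alone. Lhx8, a LIM homeobox factor in both lists, stood at 58.8 ± 3.62 CPM (SD, n = 3) in the wild type and 99.5 ± 19.6 CPM (SD, n = 3) in the knockout (adjusted p = 0.115, and 0.044 without knockout replicate 2). The anterior list had a median of 0.21 (camera, adjusted p = 0.0316, and adjusted p = 0.44 with an estimated correlation), and this call was lost without wild type replicate 2, knockout replicate 1 or knockout replicate 3 (medians 0.21, 0.081 and 0.083). Of 8 posterior palate genes, 0 passed over all genes or adjusted over the list alone, with a log2 fold change of 0.47 for Tbx3 (adjusted p = 0.273; list median -0.079, camera, adjusted p = 0.909, and median -0.23 to 3.3e-04 with single libraries left out). Of 13 tooth germ genes, 0 passed over all genes, and 2 rose and 1 fell adjusted over the list alone (median 0.22, camera, adjusted p = 0.163). The tooth germ list had a median of 0.10 without knockout replicate 2 and passed without wild type replicate 4 (median 0.27, camera, adjusted p = 0.026, and adjusted p = 0.305 with an estimated correlation).

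Lists of cell state gave 1 gene past the threshold, Btg2, an antiproliferative immediate early gene and target of p53, which fell from 28.0 ± 1.68 to 14.6 ± 2.09 CPM (SD, n = 3 each; adjusted p = 0.0451). Of 21 immediate early and dissociation stress genes, 1 fell over all genes and 2 adjusted over the list alone (median -0.19, camera, adjusted p = 0.00802, and adjusted p = 0.276 with an estimated correlation). With each library's trend with GC content and length removed, an alternative chosen after seeing the data, the median of this list shrank to -0.12 and it did not pass (adjusted p = 0.0691). Of 19 p53 targets, 1 fell over all genes and 1 adjusted over the list alone, with a median of 0.088 (-0.013 without knockout replicate 1), a mean of -0.018 and a downward test direction (camera, adjusted p = 0.691). Of 32 cell cycle genes, 0 passed over all genes or adjusted over the list alone, with 3 positive values and a median of -0.12 (camera, adjusted p = 0.0202, and adjusted p = 0.802 with an estimated correlation). Ccnd1, which encodes cyclin D1, stood at 156 ± 20.2 and 74.1 ± 27.5 CPM (SD, n = 3 each; adjusted p = 0.15, and 0.0466 without knockout replicate 3). The cell cycle call was lost without knockout replicate 2 (median 0.0088) or wild type replicate 4 (median -0.062). This median was -0.21 without knockout replicate 3. The lists of 54 ribosomal protein genes and 24 glycolysis and hypoxia genes had 0 members past the threshold over all genes or adjusted over the list alone. The ribosomal median was -0.094 (camera, adjusted p = 0.0668) and 0.14 without knockout replicate 2 (camera, adjusted p = 2.5e-04, and adjusted p = 0.654 with an estimated correlation). It was -0.27 to -0.14 without wild type replicate 2 or knockout replicate 1 or 3 (camera, adjusted p = 5.0e-05 to 0.0168, and adjusted p = 0.70 to 0.832 with an estimated correlation). The ribosomal median was -0.0398 without wild type replicate 4 (camera, adjusted p = 0.294). Rps27 had a log2 fold change of -0.85 (adjusted p = 0.433), and of -1.13 without knockout replicate 2 to -0.47 without wild type replicate 3. The glycolysis list had a median of -0.052 and a mean of 0.034 (camera, adjusted p = 0.905). Its median was 0.13 without knockout replicate 2 (adjusted p = 0.0548) and -0.16 without knockout replicate 1 (adjusted p = 0.625). Egln3 had a log2 fold change of 0.52 (adjusted p = 0.238).

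Across the 28 lists, 11 passed the competitive test with a preset correlation, 9 lower and 2 higher in the knockout. With an estimated correlation 0 lists passed (camera, 3 at an unadjusted p under 0.05), and 0 passed in the directional test (fry, 7 at an unadjusted p under 0.05). In the test for change in either direction 18 lists passed (fry). Without knockout replicate 2 these numbers were 16, 0, 1 and 19.

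**Figure D4:**
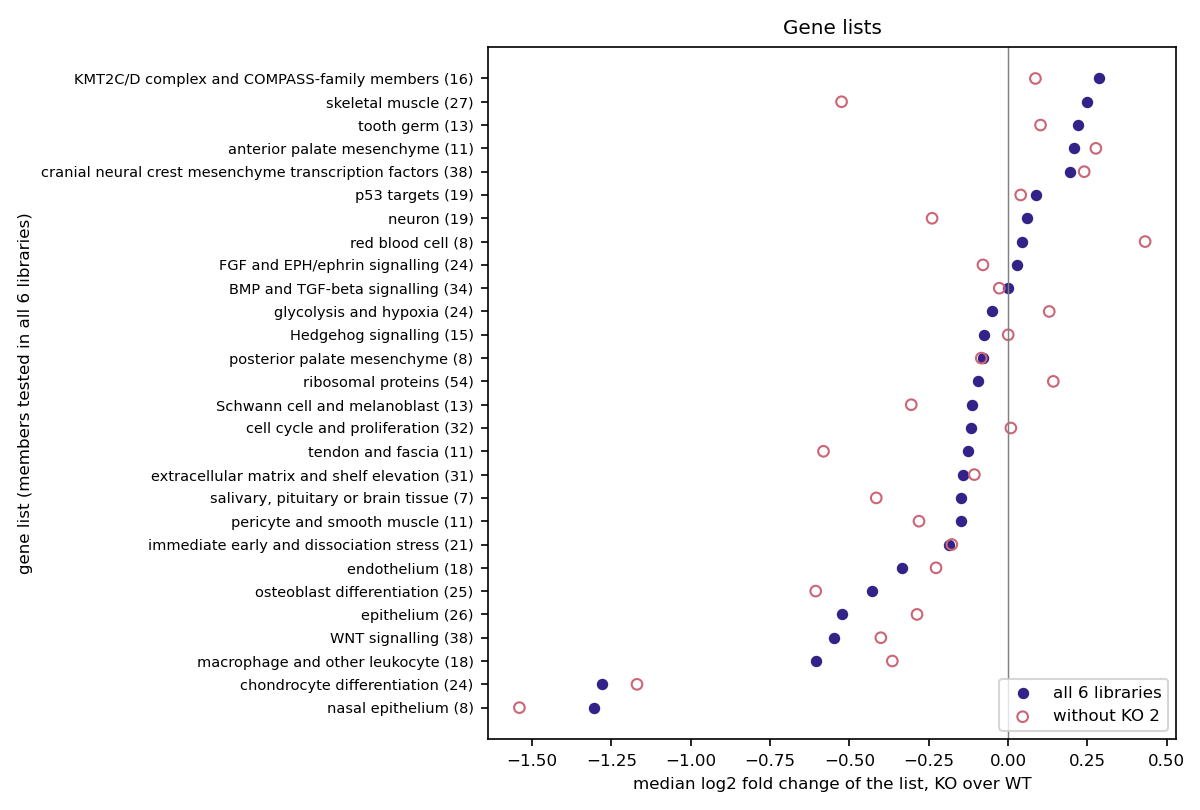
Points show the median log2 fold change of knockout over wild type for each of the 28 gene lists, with the number of tested members in brackets, for all 6 libraries (filled) and without knockout replicate 2 (open). The nasal epithelium and chondrocyte lists lie lowest with all 6 libraries, at -1.30 and -1.28, and the skeletal muscle list moves from 0.25 to -0.52.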

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

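The test of genes at 0 in the other libraries and the test of genotype, both on knockout replicate 2, were chosen only after the result was seen. In each knockout library at least 1 share of reads outside the gene counts exceeded those of all 3 wild type libraries. Pairs outside annotated genes reached 18.1% in knockout replicate 1 and 47.5% in knockout replicate 2, against at most 15.4% in the wild type. Pairs without a unique alignment reached 30.3% in knockout replicate 1 and 27.7% in knockout replicate 3, against at most 20.99% in the wild type.

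Knockout replicate 2 stood apart from the other 5 libraries in its pairs outside genes and on principal component 1. Unspliced or nuclear RNA is a candidate explanation, because its ratio to knockout replicates 1 and 3 correlated with genomic span across genes (Spearman 0.32, against -0.067 for knockout replicate 1 over 3). The same ratio correlated with transcript length (Spearman 0.37), so the trend with span is not specific to introns. Nuclear transcripts were named after their values were seen. Malat1 stood at 13718 CPM against 1254 to 3073 CPM elsewhere but Neat1 only at 14.6 CPM against 3.92 to 9.93 CPM. Kcnq1ot1, Meg3, Rian and Mirg stood at 2339, 1703, 855 and 33.1 CPM, against at most 422, 374, 378 and 9.61 CPM elsewhere. Some genomic DNA also stays open. Summed olfactory, vomeronasal and trace amine receptor CPM was 5.22 times that of the next library (95% interval 4.87 to 5.61). A count occurred in 138 of 1474 receptor genes against 20 to 30 elsewhere, but 3 genes held 3671 of 4169 counts. Of 4808 genes at 0 in the other libraries, 14.6% had a count, against 2.17% to 4.04% for the same measure elsewhere. These genes held 996 counts in total, in a library with 17693693 pairs outside genes. Pairs spread evenly over the genome would reach most such genes. The low share argues against genomic DNA as the source of most of those pairs, although no expected share was calculated. A genotype shared by the 3 knockout libraries is argued against as the whole cause, because the larger excess of knockout replicates 1 and 3 over the wild type mean in pairs outside genes was 0.118 of that of knockout replicate 2 (0.217 with 2 wild type SD added). This ratio uses the same share that set knockout replicate 2 apart, so it is not independent evidence.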

How the results depend on the processing

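The fits with sample quality weights, with Rn45s and Lars2 left out and with the GC content and length offset were chosen only after the result was seen. All 76 genes past the threshold kept their sign in each alternative that gave them a value (73 genes under the 1 CPM filter), and the median of all genes moved by less than 0.1 throughout. Because the groups did not overlap for any of the 76, their kept signs say little about robustness. For named genes, 697 alternative values kept their side of the threshold, 164 lost it, 36 gained it and 0 reversed. For lists, 430 kept their side, 32 lost it, 37 gained it and 5 reversed. Uncalled values changed sign in 24 list and 3 gene comparisons. Kmt2d stayed above 0 and past no threshold, at 0.21 to 1.04. The number of genes past the threshold, 76 in the report (14 up, 62 down), was 453 with DESeq2 (142 up, 311 down) and 40 against a 1.2-fold change (3 up, 37 down). It was 316 with quality weights (110 up, 206 down), where knockout replicate 2 had a weight of 0.178. Voom gave 9 genes up, no filter 94 down and the GC content and length offset 25 up. Other normalisations gave 71 and 78 genes, voom 60, the earlier edgeR method 68, no filter 114, the 1 CPM filter 73, Rn45s and Lars2 left out 82 and the offset 99. Leaving out single libraries gave 0 to 307 genes, 0 to 80 up and 0 to 227 down. A fit with fewer libraries has fewer degrees of freedom, so the low end can come from that. The high end came without knockout replicate 2. Lists past the threshold numbered 0 with an estimated correlation and 0 with fry, and 11 to 16 otherwise. The ribosomal list reversed to 0.14 and the skeletal muscle list to -0.52 without knockout replicate 2, within ranges of -0.27 to 0.14 and -0.52 to 0.60 over single libraries left out. With quality weights the ribosomal, skeletal muscle and neuronal lists reversed to 0.11, -0.27 and -0.44, in a fit that takes weight from that library. The cause of the other shifts was not tested. Depth limited genes near 1 count per library, such as Bpifa1 in the knockout.

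With the replicate number as a block, 301 genes passed (105 up, 196 down), 64 of them among the 76, and 16 lists passed. Knockout replicate 1 and wild type replicate 4 have numbers found in a single group, so they did not inform the group difference here. It rested on the libraries numbered 2 and 3, knockout replicate 2 among them, with few degrees of freedom. The larger count is therefore not a sign of a more sensitive comparison. The anterior palate list lost its call in this fit (median 0.088, camera, adjusted p = 0.133). The numbers 2 and 3 occur in both groups, and deviations of same-numbered libraries correlated at 0.21 and -0.14, so the numbers were not taken to pair the samples.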

Other observations

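The gene groups first drawn up in this part, the genes named for them, the test of the chondrocyte list without wild type replicate 2 and the fits with the GC content and length offset and with Rn45s and Lars2 left out were chosen only after the result was seen. Crabp2, Aldh1a1 and Adh1, all genes of retinoid handling, fell in the knockout, 3 of 21 tested genes of retinoid binding, synthesis and receptors, of which 0 rose. Crabp2, a cellular retinoic acid binding protein, fell from 71.2 ± 7.91 to 24.6 ± 6.37 CPM (SD, n = 3 each; edgeR adjusted p = 0.0342), and Aldh1a1, a retinaldehyde dehydrogenase, fell from 5.19 ± 1.17 to 1.30 ± 0.298 CPM (SD, n = 3 each; adjusted p = 0.0451). Adh1, an alcohol dehydrogenase that oxidises retinol, fell from 0.99 ± 0.556 to 0.0647 ± 0.0103 CPM (SD, n = 3 each; log2 fold change -3.86, adjusted p = 0.0471, and -3.996 with adjusted p = 0.0703 without knockout replicate 2). The list had a median log2 fold change of -0.22, and 5 members fell without knockout replicate 2. Of 40 collagen genes 2 fell, Col1a1 and Col8a2, the latter from 138 ± 29.1 to 47.3 ± 7.53 CPM (SD, n = 3 each; adjusted p = 0.0254). The collagen list had a median of -0.34, and without knockout replicate 2 a median of -0.44 with 3 members that fell. Because these lists were drawn up after their members' values were seen, no test of the lists is given.

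Among 46 genes for glutamate and GABA receptors and synaptic adhesion, 5 rose and 1 fell, with a median of 0.73. Those that rose were Gria4, Gabra3, Lrrtm3, Lrrc4c and Cbln4, and Lrrc4b fell from 27.4 ± 2.54 to 14.34 ± 0.644 CPM (SD, n = 3 each; adjusted p = 0.0352). Without knockout replicate 2, 10 rose and 2 fell and the median was 0.44. In the neuronal marker list 0 of 19 genes passed, with a median of 0.059. Of 48 replication-dependent histone genes, 0 passed, with a median of 1.10, and 7 were higher past the threshold without knockout replicate 2 (median 1.34). Values of these multicopy genes are uncertain, because pairs without a unique alignment were set aside. Such pairs made up 30.3% and 27.7% in knockout replicates 1 and 3 against at most 20.99% in the wild type. The cause of the higher histone values was not tested. Of 14 imprinted growth genes, 1 fell, the cyclin-dependent kinase inhibitor Cdkn1c, from 674 ± 44.7 to 405 ± 26.6 CPM (SD, n = 3 each; adjusted p = 0.0471). The imprinted list had a median of 0.028, and of -0.12 without knockout replicate 2, with 1 higher and 2 lower past the threshold.

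The 62 genes that fell were richer in GC, with a median transcript GC content of 54.9% against 49.7% over tested genes and 44.3% in the 14 that rose. A trend with GC content and length is argued against as the whole of the fall, since removing it kept 0.935 of the median log2 fold change, with 57 of the 62 still past the threshold. Leaving out knockout replicate 2 kept 0.96 (59 of 62 past), and leaving out Rn45s and Lars2 kept 1.02 (62 of 62 past). The groups did not overlap for these 62 genes, so leaving out 1 library could shrink the fall but hardly reverse it. Leaving out Rn45s and Lars2 changes only library sizes and normalisation, so it does not address other differences in RNA between the groups. The loss of Kmt2d, which the design names, and a batch that follows the groups both stay open and untested, since the labels give no batch and exon-level counts were not analysed here.

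The lower chondrocyte list may rest in part on wild type replicate 2, whose cartilage matrix gene Matn1 stood at 23.8 CPM against 5.74 and 4.69 CPM in wild type replicates 3 and 4. Without that library the median kept 0.515 of its size, -0.66 against -1.28, and with each other library left out it lay between -1.17 and -1.51. How much cartilage each dissection held, as opposed to expression per cell, cannot be told apart from genotype with 3 libraries per group.

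The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 76 genes (14 up, 62 down) and the highest other split 0, so that 1 split of 10 gave as many in each of these counts. Every other split mixes wild type and knockout libraries, so any difference between the groups widens its spread within groups and lowers its calls. The contrast of 76 with 0 therefore does not measure what chance gives. For lists, the real split gave 11 and the highest other split 15, and 6 of the 10 gave at least as many as the real one.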
